A study of Biomphalaria glabrata with 7 samples.

How the data were processed

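The series holds 7 two-colour arrays of BS90 snails. Per the labels, each sample was total RNA from a pool of 5 snails, 50 ng of which was copied and labelled with Cy5, and the reference was labelled with Cy3. Per the file headers and the submitters' processing notes, the images were read with Agilent Feature Extraction 10.5.1.1. The deposited files give the intensity of each spot on a linear scale, as mean signal, local background and processed signal. The deposited log10 ratio is log10 of Cy5 over Cy3, and the authors' value table equals it within a tolerance of 1e-06, so its scale and direction are settled. Its median was 0 on each array. Each file holds 31966 spots, 30647 of them probes of 60 nt and 1319 controls. No probe was saturated. The files describe all 30647 probes as Unknown, and the gene table provided could not be joined to them, so only probe names that hold a gene name are named here.

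Intensities were background-corrected with normexp (offset 50) and normalised by loess within each array, with control spots at weight 0, in R 4.3.3 with limma 3.58.1. Spots with outlier flags were removed, between 1 and 80 per array. Probes well above background in Cy5 on at least 2 arrays were kept. A group-means model over all 7 arrays was fitted with lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg within each comparison. All tests were two-sided. Values are log2 ratios to the reference, and SE is the moderated standard error. Where a probe was not well above background on any array of a group, a bound was computed from the Cy5 channel after loess and Aquantile, which is open to dye bias because no dyes were swapped. It is given below for BgMFREP1_1. On simulated arrays of 20212 probes with 100 probes changed by 1 and 100 by 2 on the log2 scale, 90% and 100% were recovered for injury against untreated, 87% and 100% for septic injury against untreated, and 92% and 99% for septic injury against injury. Unchanged probes called falsely numbered 16, 11 and 19. The simulated noise was independent between probes and held no slide effect, unlike the arrays measured.

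The rule for named probes, set before the data were examined, took for each comparison the 10 largest rises and 10 largest falls among probes named for a protein that passed and whose arrays did not overlap. Where fewer than 5 passed, the 5 smallest p-values among the others were added, and at most 2 rising and 2 falling unnamed probes were allowed. Probes with the prefix BGNS or BGNAS and those named for mitochondrial rRNA are outside the rule and were chosen after their values were seen. The 32 gene lists fixed beforehand could not be tested, because 2 matched any probe name and neither had over 1 kept probe. Groups of probes by name (FREP and Fibro, Toll-like receptor, NADPH oxidase, NF-kB and IKK, nitric oxide synthase, mitochondrial protein genes, mitochondrial rRNA, and the prefixes BGNS, BGNAS, Sm and Ep) were formed in their place after the data were seen. The files do not explain these prefixes. Groups with at least 5 kept probes were tested with camera (preset correlation 0.01), with an estimated correlation and with fry. The nitric oxide synthase probe was not well above background on any array.

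Slide, scan and slide row came from the file headers. Alternatives were other background corrections, normalisations, filters, variance models, thresholds, the Cy5 channel alone, the authors' value table, the replicate number as a block and each array left out. GC content, slide row, a stricter filter on processed signals, the simulated overlap of calls, the split of the untreated arrays and the size of change under settings with fewer calls were added after the data were seen. Sequence matches between probes used blastn 2.17.0.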

Results

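Whole-body RNA of the freshwater snail *Biomphalaria glabrata* was measured on 7 oligonucleotide arrays to ask how untreated snails, snails injured with a hypodermic needle and snails given a septic injury by injection of bacteria differ at 12 h. All snails were adults of the BS90 strain with shells of 10 to 12 mm, and each array held RNA from a pool of 5 snails, labelled with Cy5. The same Cy3-labelled pool, made from several strains, was the reference on every array, so each value is a log2 ratio of a sample to that pool. The groups held 2 untreated, 3 injury and 2 septic injury pools, which the labels call biological replicates. Between 16170 and 19332 of the 30647 probes were well above background in Cy5 on an array, and 20212 passed the filter. The number of arrays limits the precision. The untreated label also says sham exposed, and the bacteria are not named in the labels. Both untreated arrays were on slide 2 and all injury and septic injury arrays on slide 1, so slide and treatment cannot be told apart in either comparison with untreated snails. Septic injury against injury lies within slide 1. Both septic arrays and 1 injury array were in row 2 of that slide, and the other 2 injury arrays were in row 1. Slide row and septic injury are therefore partly confounded.

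The first comparison asked what injury changed. Of 8 tested probes named for fibrinogen-related proteins (FREPs), a family of snail plasma lectins, 7 were higher in injured than in untreated snails. BgMFREP2_1 was 10.55-fold higher, at 2.54 ± 0.31 (SD, n = 3) against −0.86 ± 0.33 (SD, n = 2), a log2 change of 3.40 with a standard error of 0.21 and a limma adjusted p of 9.51e-05. BgMFREP6 was 5.97-fold higher (1.85 ± 0.46, n = 3, against −0.73 ± 0.28, n = 2; adjusted p = 0.000284). BgMFREP5 was 3.43-fold higher (adjusted p = 0.00131) and BgMFREP4_1 was 3.90-fold higher (adjusted p = 0.0187), although the SD of BgMFREP4_1 between injury pools was 0.97. Of the 9 measured probes in the FREP and Fibro name group, 7 rose, none fell and 2 did not pass. BgMFREP8, FREP12_1 and BgMFREP9 were the other members that rose, with log2 changes of 0.81, 0.76 and 0.58. With median centring in place of loess the change of BgMFREP9 was 0.0048 and that of BgMFREP8 was 0.53 (adjusted p = 0.051). BgMFREP4_1, FREP12_1 and BgMFREP9 did not pass without untreated replicate 1 or without untreated replicate 2, nor did BgMFREP8 without untreated replicate 1. In these fits the lone untreated array is assumed to vary like the other groups, and the changes of BgMFREP4_1 were 1.79 and 2.14. Untreated replicates 1 and 2 read −1.21 and −1.25 for FREP12_1, −1.28 and −1.35 for BgMFREP9, and 0.11 and 0.53 for BgMFREP8. The group was shifted upward by camera (adjusted p = 4.08e-05), but the adjusted p was 0.0568 with an estimated correlation, which was −0.057. By fry the adjusted p was 0.000222. The group was formed from probe names after the files were seen.

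**Figure D1:**
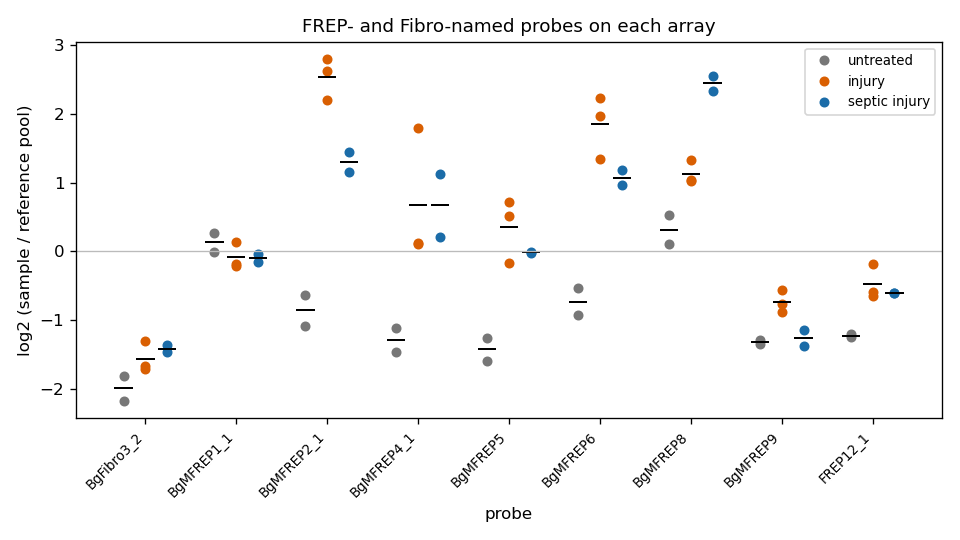
Log2 ratio of sample to reference pool (vertical axis) for each measured FREP- or Fibro-named probe (horizontal axis), with 1 point per array and a black bar at each group mean. BgMFREP2_1 has a mean of 2.54 in injury, 1.31 in septic injury and −0.86 in untreated snails.

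Probes named for mitochondrial protein genes moved in both directions. Of 13, 4 rose, 2 fell and 7 did not pass after injury. BGM_ND2, named for a subunit of respiratory complex I, was 2.53-fold higher (log2 change 1.34, SE 0.16, adjusted p = 0.00102). Its spot was flagged on injury replicate 1, so its injury mean rests on 2 pools. BGM_ND4 was 2.09-fold higher (adjusted p = 0.0348). BGM_ND6 was 5.73-fold lower, at −2.26 ± 0.11 (SD, n = 3) against 0.26 ± 0.37 (SD, n = 2), with an adjusted p of 0.000103. BGM_ND5 was 2.14-fold lower (adjusted p = 0.00098). The group as a whole did not shift by camera (adjusted p = 0.59). BGM_ND4 lost its call with median centring (log2 change 0.38) and without untreated replicate 1 (0.52).

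Of 4 probes named for NF-kB or its kinase IKK, a signalling pathway of innate immunity, 1 rose and 1 fell. Bg_IPT_NFkB_21sd03877 was 1.67-fold higher (adjusted p = 0.0434) and Bg_IPT_NFkB_ACN73461_21sd56333 was 1.61-fold lower (adjusted p = 0.00825). Of 8 probes named for phox subunits of NADPH oxidase, the enzyme of the oxidative burst, only Bg_SH3_p47phox_21sd11058 passed, 1.51-fold lower (adjusted p = 0.00959). Bg_putp22phox_21sd10841 was well above background in Cy5 on every injury array and on no untreated array. The same held in Cy3, which carried the reference pool. Bg_IPT_NFkB_21sd03877 and Bg_SH3_p47phox_21sd11058 did not pass without untreated replicate 1 (log2 changes 0.72 and −0.57) or without untreated replicate 2 (0.77 and −0.63), nor did Bg_IPT_NFkB_ACN73461_21sd56333 without untreated replicate 2 (−0.53). Neither of the 2 measured Toll-like receptor probes passed, and BgTLR_21sd08246 had a log2 change of 0.59 (adjusted p = 0.0582).

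Over all probes, 4813 of 20208 differed between injured and untreated snails at an adjusted p under 0.05 in limma, 2122 higher and 2691 lower. Of these, 1129 changed at least 2-fold. The largest fall of an unnamed probe was 16.2-fold, for c2871_rc. The unnamed probe c35019 rose 16.1-fold (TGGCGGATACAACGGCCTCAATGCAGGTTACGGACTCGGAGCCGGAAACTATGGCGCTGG). Probe contig_4669_rc fell 14.4-fold (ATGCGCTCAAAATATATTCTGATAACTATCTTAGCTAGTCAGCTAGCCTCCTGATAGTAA). With median centring the share of higher probes among the called ones was 27.8% in place of 44.1%, and the median of all probes was −0.12. Without untreated replicate 1 or 2 the count was 2290 or 2280, from 1 untreated array assumed to vary like the other groups.

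Septic injury was compared with untreated snails in the same way. Of the 9 measured FREP- and Fibro-named probes, 6 were again higher, none passed as lower and 3 did not pass. BgMFREP2_1 was 4.48-fold higher (1.31 ± 0.21, n = 2, against −0.86 ± 0.33, n = 2; adjusted p = 0.000482). BgMFREP8 was 4.36-fold higher, at 2.44 ± 0.15 (SD, n = 2) against 0.32 ± 0.30 (SD, n = 2), with a limma adjusted p of 0.0002. BgMFREP4_1, BgMFREP6, BgMFREP5 and FREP12_1 were 3.89-, 3.49-, 2.66- and 1.54-fold higher. BgMFREP1_1 was not well above background on either septic array. Its Cy5 signal was at least 1.32-fold brighter in untreated snails, a bound on that channel alone and not on the ratio to the reference, which was 1.17-fold higher in untreated snails and did not pass (adjusted p = 0.37). The group's camera adjusted p was 0.000611, and the adjusted p was 0.0937 with an estimated correlation and 0.00057 by fry.

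Of the 13 mitochondrial protein probes, 5 rose, 2 fell and 6 did not pass. BGM_ND2 was 2.96-fold, BGM_ND4 2.86-fold and BGM_CYTB, named for cytochrome b, 2.08-fold higher. BGM_ND6 was 4.11-fold lower (adjusted p = 0.000257). Bg_IPT_NFkB_21sd03877 was 2.15-fold higher (adjusted p = 0.0128) and Bg_IPT_NFkB_ACN73461_21sd56333 was 1.62-fold lower (adjusted p = 0.0113). Among phox-named probes, BgPhox91_21sd05363 and Bg_SH3_p47phox_21sd11058 were 1.45- and 1.36-fold lower. Several calls were lost in fits where a lone array is assumed to vary like the other groups. Bg_IPT_NFkB_21sd03877, BgPhox91_21sd05363 (log2 change −0.54 in the main fit), Bg_SH3_p47phox_21sd11058 (−0.45) and BgMFREP4_1 (1.96) did not pass without untreated replicate 1 (1.08, −0.63, −0.41 and 1.78), without untreated replicate 2 (1.13, −0.45, −0.48 and 2.13) or without septic injury replicate 2 (0.83, −0.61, −0.44 and 1.501). Bg_IPT_NFkB_ACN73461_21sd56333 (−0.69) did not pass without untreated replicate 2 (−0.54) or without septic injury replicate 2 (−0.62). Both phox-named probes also did not pass without septic injury replicate 1 (−0.46 and −0.46). BGM_ND4 (1.52) did not pass without untreated replicate 1 (0.97) or without septic injury replicate 1 (1.30). With median centring BGM_CYTB (log2 change 0.53) and BGM_ND1 (0.39) lost their calls.

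**Figure D2:**
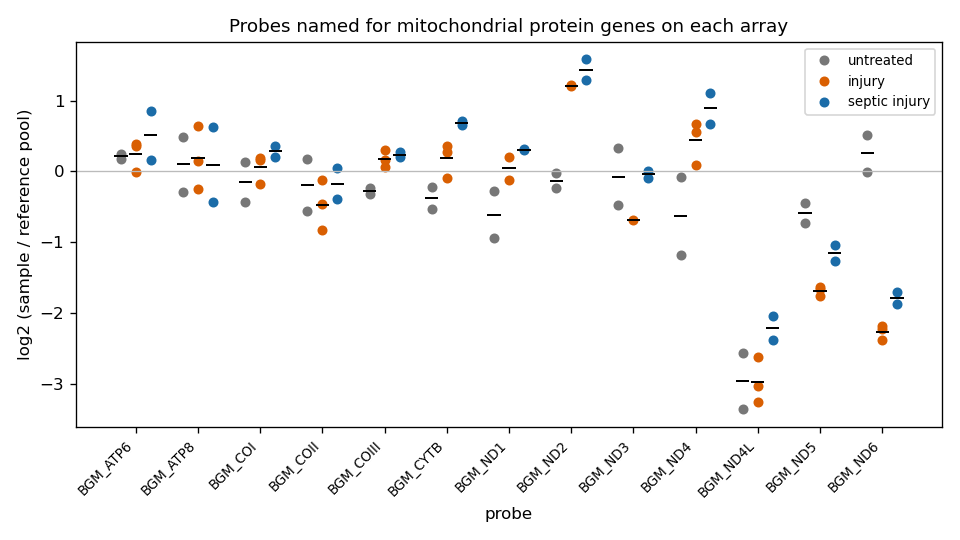
Log2 ratio of sample to reference pool (vertical axis) for the 13 probes named for mitochondrial protein genes (horizontal axis). There is 1 point per array where the spot was not flagged, and a black bar at each group mean. BGM_ND6 is lower in injury (mean −2.26) and septic injury (mean −1.78) than in untreated snails (mean 0.26).

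In all, 5086 of 20188 probes differed between septic and untreated snails, 2386 higher and 2700 lower, and 1392 changed at least 2-fold. The largest changes of unnamed probes were those of contig_3280_rc (22.9-fold higher) and lrc38125 (15.5-fold lower). The unnamed probe contig_1276 rose 19.2-fold (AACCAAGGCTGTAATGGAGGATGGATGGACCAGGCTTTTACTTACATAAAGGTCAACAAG), and contig_4395_rc fell 12.5-fold (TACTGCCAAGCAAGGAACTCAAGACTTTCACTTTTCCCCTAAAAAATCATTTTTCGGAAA). With median centring 27.2% of called probes were higher in place of 46.9%. The count was 3241 with the Cy5 channel alone, 2414 or 2877 without untreated replicate 1 or 2, and 3003 or 2521 without septic injury replicate 1 or 2, each from a lone array assumed to vary like the other groups.

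The remaining comparison asked how septic injury differed from injury, within slide 1. BgMFREP8 was 2.49-fold higher after septic injury (2.44 ± 0.15, n = 2, against 1.13 ± 0.17, n = 3; limma adjusted p = 0.00971). BgMFREP2_1 was 2.35-fold lower (1.31 ± 0.21, n = 2, against 2.54 ± 0.31, n = 3; adjusted p = 0.0172). The other 7 measured FREP and Fibro probes did not pass, and the group did not shift (camera adjusted p = 0.253). BgMFREP6 and BgMFREP9 had log2 changes of −0.78 and −0.52 with adjusted p of 0.0968 and 0.0624. With the scanner software's processed signals the log2 change of BgMFREP8 was 1.36 (adjusted p = 0.0595) and that of BgMFREP2_1 was −1.29 (adjusted p = 0.0779). Without septic injury replicate 2 the changes were 1.21 and −1.09 and neither passed (adjusted p = 0.1 and 0.16), with 1 septic array assumed to vary like the other groups. BgMFREP2_1 also missed the threshold without septic injury replicate 1 (−1.38, adjusted p = 0.0517) and without injury replicate 2 (−1.19, adjusted p = 0.0561).

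None of the 13 mitochondrial protein probes passed singly. As a group they were higher after septic injury by camera (adjusted p = 0.00225), with a median log2 change of 0.29. The adjusted p was 0.395 with an estimated correlation and 0.192 by fry, so neither passed. BGM_ND5, BGM_CYTB and BGM_ND4L had log2 changes of 0.53, 0.50 and 0.75 with adjusted p of 0.0583, 0.107 and 0.115. No NF-kB, phox or Toll-like receptor probe passed.

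In this comparison 1254 of 20185 probes differed, 778 higher and 476 lower after septic injury. Of the 778, 440 were above untreated snails after septic injury and 241 were below them after injury. Of the 476, 231 were below untreated snails after septic injury and 171 were above them after injury. A difference from injury thus need not be a change added to that of injury, and these counts against untreated snails cross slides. The unnamed probe c262 rose 5.60-fold (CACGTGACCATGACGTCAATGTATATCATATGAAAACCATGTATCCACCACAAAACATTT). Probes lrc22180_rc and lrc10023, which hold the same sequence, fell 6.92- and 6.86-fold (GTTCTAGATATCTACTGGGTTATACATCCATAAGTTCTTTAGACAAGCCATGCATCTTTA), with SDs of 1.32 and 1.45 between the 2 septic pools. Their log2 changes of −2.79 and −2.78 became −1.85 and −1.75 without septic injury replicate 1, and −3.73 and −3.81 without septic injury replicate 2. All 3 probes lost their calls with processed signals, c262 also without either septic array, and lrc10023 also without injury replicate 2. For c262 the septic pools read 1.53 ± 0.18 (SD, n = 2) against −0.96 ± 0.64 (SD, n = 3) in injury, so its septic values lay close together. The count was 75 (45.3% higher in place of 62.0%) with processed signals, 8 with slide row as a block, 343 within slide row 2 and 16 without septic injury replicate 2. The last 3 fits rest on 1 injury array in row 2 or on 1 septic array, which is assumed to vary like the other arrays, so they do not test single pools. Over the 1254 called probes the median change was 0.76 in the main fit and 0.76, 0.76 and 0.70 in these 3. The median standard error was 0.15 and then 0.20, 0.19 and 0.18. These probes were chosen for their change on the same arrays, which favours a similar median. It therefore does not decide whether the fall in calls is lost precision alone.

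Changes against untreated snails after injury and after septic injury were compared probe by probe. Across 20185 probes, which are not independent replicates, the Pearson correlation of the log2 changes was 0.78. Simulated groups with no effect against the same 2 untreated arrays gave a mean of 0.55. The covariance was 0.23 against a simulated 0.018. Both comparisons called 1223 probes higher and 1741 lower, and 8 probes were called in opposite directions. In 100 simulations of groups with no effect against the same untreated arrays, lists of these lengths shared 865.3 higher and 1099 lower probes on average (at most 913 and 1159), while 0.01 and 0.06 on average passed the threshold in both. This simulation was added after the data were seen. Independent lists would share 250.3 and 359.0. The simulated values leave out the effects and the independent ones leave out the shared arrays, so the excess over either is not a measure of a shared effect. The 2 untreated arrays cannot be split into groups of 2, so part of the excess over independent lists may come from sharing them. The simulated covariance of 0.018, which includes this sharing, was small beside the observed 0.23. With each comparison against a different single untreated array, added after the data were seen, the correlation was 0.71 or 0.64 and the covariance 0.22 or 0.21. Both comparisons still share the slide difference.

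**Figure D3:**
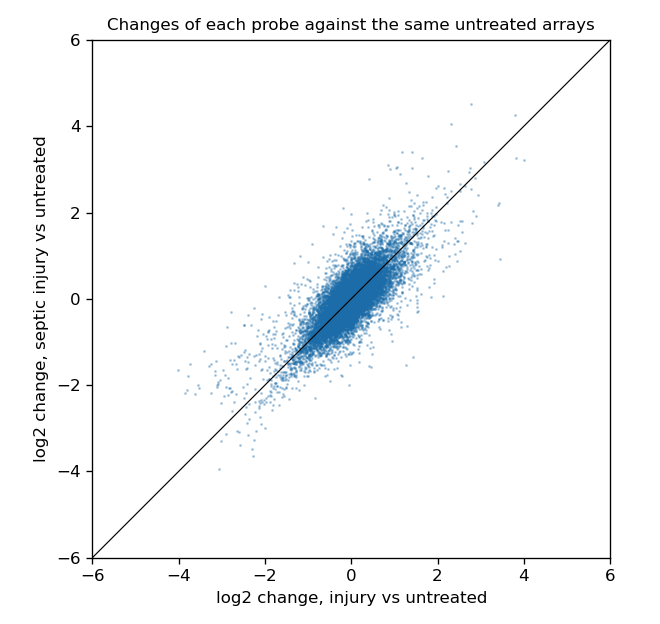
Log2 change of each probe after injury (horizontal axis) and after septic injury (vertical axis), both against the same 2 untreated arrays, with 1 point per probe and a line of equality. The points follow the line with a Pearson correlation of 0.78, against 0.55 simulated for no effect.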

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

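The GC content, slide row, stricter processed-signal and single-control settings were chosen after seeing the data. Fits without an untreated or septic array, with slide row as a block or within row 2 leave an arm of 1 array, assumed to vary like the others. No called probe taken by the rule and no called name group changed direction under the settings run for it. For probes these were median centring, processed signals, no filter, the replicate block and each array left out. Groups were also run with the Cy5 channel alone, a single probe per name, an estimated correlation and fry. The BGNS, BGNAS and mitochondrial rRNA probes were not refitted singly. Probes changed in injury against untreated stayed within 1.5 times of 4813 except at unadjusted p under 0.05 with 2-fold (1175) and without single arrays (2280 to 5055, lowest without untreated replicate 2). Septic injury against untreated moved from 5086 to 3241 with the Cy5 channel alone, 1443 at unadjusted p with 2-fold, and 2414 to 6043 without single arrays. Septic injury against injury moved from 1254 to 75 with processed signals and 75 with the authors' value table, 832 with processed signals of probes well above background in both channels on all 7 arrays, 672 with the replicate block, 715 with the groups compared alone, 2542 at adjusted p under 0.10, 366 at unadjusted p with 2-fold, 8 with slide row as a block (2998 at unadjusted p under 0.05), 343 within slide row 2, and 16 to 1538 without single arrays (317 without injury replicate 2, 707 without injury replicate 3, 355 without septic injury replicate 1, 16 without septic injury replicate 2). Leaving out an untreated array gave 715 there, since fewer arrays set the spread. The cause of the other moves was not tested. Aquantile left every ratio unchanged by construction. The fold change correlation ranged from 0.717 (without septic injury replicate 1) to 0.797 without single arrays. Same-numbered samples did not deviate together (correlations of deviations from −0.026 to 0.087), so no shared effect of the number was seen. With so few arrays in a group, that does not settle whether the numbers pair the samples. The replicate block gave 3784, 4761 and 672 calls. Slide could not be fitted as a block: each untreated comparison is wholly confounded with it and the other lies within 1 slide. Dim signal limits the results, since 10435 probes were left out by the filter.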

Other observations

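All tests here were chosen after the results they bear on had been seen, except the median row difference over the called probes and the reference channel test on FREP-named probes. Those were written before their own values were seen, but after fits with slide row and the reference channel over all probes had been, and the name group, the slide row settings and the size-ranked row difference were all chosen after the data were seen. The probes with the prefix BGNS or BGNAS have names ending in 18S, 28S, 5_8S, ITS1 or ITS2, parts of the nuclear ribosomal RNA unit. The files do not explain these prefixes, so whether both read ribosomal RNA levels is not known. After injury BGNS_18S was 4.58-fold and BGNS_ITS2 3.64-fold higher than in untreated snails (limma adjusted p = 0.00122 and 0.000931), and the other 3 BGNS probes did not pass. After septic injury BGNS_ITS2 was 4.19-fold higher (adjusted p = 0.000987) and BGNS_28S 2.76-fold lower (adjusted p = 0.00797) than in untreated snails, and the other 3 BGNS probes did not pass. In the same comparison 4 of the 5 BGNAS probes were lower than in untreated snails, from BGNAS_18S (2.35-fold) to BGNAS_5_8S (2.45-fold). Against injury 4 BGNAS probes, BGNS_18S (2.74-fold) and BGNS_28S (3.15-fold) were lower after septic injury. The BGNAS group had a camera adjusted p of 0.000221 there with the preset correlation of 0.01. The adjusted p was 0.395 with an estimated correlation, which was 0.50, and 0.0647 by fry. Against untreated snails the camera adjusted p was 0.00203 after septic injury (adjusted p = 0.345 with an estimated correlation and 0.0226 by fry) and 0.59 after injury. The BGNS group did not pass in any comparison (adjusted p = 0.131, 0.706 and 0.244), nor did the NADPH oxidase group (0.823, 0.746 and 0.282). Neither of the 2 mitochondrial rRNA probes passed in any comparison.

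Of 26 probes with the prefix Sm, 23 were well above background in Cy3 on all 7 arrays and 4 in Cy5. Their median log2 ratio was −2.73 and the lowest −5.71. The 4 in Cy5 were Sm_18S, Sm_28S, Sm_5_8S and SmspSSHD03, and the highest mean log2 ratio of an Sm probe was 0.31. Of the 17 tested, 4 were higher after injury than in untreated snails, 1 (Sm_18S) was higher after septic injury than in untreated snails and 2 were lower after septic injury than after injury. The camera adjusted p values were 0.00356, 0.886 and 0.00144. The adjusted p values were 0.578, 0.958 and 0.395 with an estimated correlation, which was 0.42, and 0.149, 0.974 and 0.16 by fry. SmM_COII, SmM_ND3, SmM_ND4, SmM_ND4L, SmM_ND5, SmM_ND6 and Sm_COB were well above background in Cy5 on injury arrays alone. The filter thus kept them through the group where they read high. The group's rise after injury and its lower values after septic injury than after injury cannot be taken as support for a change. Of 12 probes with the prefix Ep, none of the 4 tested passed in any comparison, and 3 of the 12 were well above background on all arrays in each channel. E1A control spots read 8.67-fold higher in Cy5 on the untreated arrays than on the others, and 1.17-fold higher in Cy3. Among pairs of probes matching over at least 40 nt at 95% identity, log2 changes correlated at 0.911, 0.929 and 0.916 over 125 same-strand pairs, for injury and septic injury against untreated and septic injury against injury. Over 27 opposite-strand pairs they correlated at 0.33, 0.0093 and 0.076.

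In all, 4813 probes differed between injured and untreated snails. Over the called probes the Cy5 channel alone moved by 89.1% of the median ratio change. They were chosen for their ratio on the same spots, which favours this, so that share does not measure the part of the reference channel. In the Cy5 channel alone 2978 of the 4813 were called, which argues against a shift of the reference channel as the whole cause for these. Over the 4813 the median Cy3 change, signed by the direction of the ratio change, was −0.13. A part from the reference channel thus stays open. A trend on GC content as the whole cause is argued against as well, with 4440 calls after its removal, 3471 of them shared. Slide, scan and labelling cannot be told apart from injury, because no slide holds both groups and the reference channel alone, which held the same pool, differed at 4678 probes between slides and at 0 between septic injury and injury (1422 at unadjusted p under 0.05, limma). Injury itself stays open as an untested explanation of any share of these differences.

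Septic injury and injury differed at 1254 probes. If slide row were the cause, the injury array of row 2 would lie toward the septic arrays; its median difference from row 1 was −0.18% of the septic change. Calls require a small spread within injury, which favours that outcome, so the same was computed for as many probes ranked by size alone: 0.036 against 0.85 on the log2 scale. With row as a block, which leaves 1 injury array beside the septic arrays, the median change was 0.76 over the called probes and calls fell to 8. With processed signals calls fell to 75, and the cause of this fall was not tested. Over the 1254 called probes the median standard error went from 0.15 to 0.25. Their median change went from 0.76 to 1.06 (139.9%, 100% with the same sign). These probes were chosen for their change on the same spots, so the persistence of their median change does not decide whether the background correction contributed. For the same reason the median change with row as a block does not decide whether slide row contributed. Of the 1254 probes, 1235 were called again without background correction and 45 with processed signals. Among 10 splits of the 5 arrays, 1 split, the real one, gave as many as 715 calls and the highest other gave 0. Those 10 splits are too few for a share under 0.05.

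Of 9 measured probes in the FREP and Fibro group, 7 were higher in injured than in untreated snails and 2 did not pass, and the group's adjusted p was 0.0568 with an estimated correlation. The reference channel fell by 0.24% of the median ratio change over the 7 called probes, with single probes from −0.43 to 0.14 on the log2 scale. This argues against a reference shift as the source of the median rise of 1.78. It does not decide for BgMFREP8, FREP12_1 and BgMFREP9, which rose by 0.81, 0.76 and 0.58, because a change of −0.43 is not small beside these. Between septic injury and injury BgMFREP8 and BgMFREP2_1 passed in opposite directions, 2.55 apart on the log2 scale, and no other member passed. Neither call held with processed signals (1.36 and −1.29). Without septic injury replicate 2, which leaves 1 septic array, the changes were 1.21 and −1.09. Because this is not the comparison with untreated snails, it does not decide whether 1 signal shared by all members lay behind the rise. Slide and labelling cannot be told apart from injury for these 7 probes. Injury itself stays open for them and was not tested apart from slide, since no untreated and injured pools shared a slide and no dyes were swapped.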
